A study of Danio rerio with 2 samples.

How the data were processed

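The samples were 2 10x Genomics 3′ single-cell libraries, 1 of fxr wild-type and 1 of fxr mutant zebrafish larvae at 6 days after fertilisation. Cells of 600 to 700 dissociated larvae were sorted side by side for GFP from a cldn15la reporter and against 7-AAD, which marks dead cells, and 10000 cells were loaded per library. Each sample was assigned to its genotype from its labels. With 1 library per genotype there is no replicate and no batch within a genotype, so genotype and library are the same split, and no paired analysis, test, p-value or count of differing genes was computed.

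The count matrices deposited by the authors hold whole UMI counts per gene and cell, with no normalisation. They were made with Cell Ranger, whose version is not given in the sources used here, and Seurat 3.1.0 on the danRer11 genome, as the submitters' processing notes name them. The deposited cell table gives, per the file headers, the counts of UMIs and genes of each cell, the percent of its UMIs from mitochondrial genes, its library and a cluster number. Recomputed sums of the matrices matched the deposited counts and the deposited percent for all 9918 cells. No cell has over 2999 genes or over 25.0% mitochondrial UMIs, so the authors left out cells above such limits. The clusters are numbered 0 to 26 with no names and were made on the integrated data of both libraries, per the file headers. A combined matrix with the same columns as the single ones was not used here. Genes are given by symbol only, and 6639 of the 18340 symbols are in the gene name table. Genome positions were not used here.

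The wild-type library holds 21975754 UMIs in 4710 cells, from 455 to 28898 per cell, and the mutant library 29870229 UMIs in 5208 cells, from 498 to 29844 per cell. The mutant over wild-type ratio is 1.36 for total UMIs and 1.32 for the median UMIs per cell. Absorptive cells hold 1591550 wild-type and 3318340 mutant UMIs.

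Counts were summed over the cells of a set in each library and scaled to 1000000 UMIs of that set (CPM). A ratio is mutant over wild-type CPM, with an exact conditional binomial 95% interval. Counts have exact Poisson intervals and shares exact Clopper-Pearson intervals. Neither covers variation between larvae, pools or library preparations, and those of counts and ratios do not cover uneven levels between cells. No fold is given where both libraries have 3 or fewer counts. Sets were all cells, absorptive cells (the enterocyte-like and the ileocyte- and lysosome-rich-like clusters), and each cluster with at least 100 (absorptive) or 50 (other) cells per library, 17 in all; cluster 17 is under this minimum and was added after its size was seen.

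Clusters were named from 23 marker sets fixed before the data were examined, as were the gene lists, the sets of cells, the rules for naming genes and most alternatives. A cluster took the name of a marker set when at least 3 of its markers, and at least 40% of those measured, were over 2-fold above the other cells, with 10 CPM added to both sides and the gene's 2 highest cells left out. These naming limits were set with the data in hand, and the pancreatic islet set, whose markers enteroendocrine cells share, was not used for naming. This named 20 clusters and left 7 unnamed. Clusters 18 and 19 are compared by number only. Gene names were chosen by rule: measured members of the Fxr and bile salt handling list; the 12 highest and 12 lowest ratios of absorptive cells among genes with at least 50 CPM in either library; the 5 highest and 5 lowest of each cluster with at least 100 CPM; the 8 highest and 8 lowest over all cells with at least 50 CPM; and the 2 highest and 2 lowest of each list in absorptive cells. Ranking was by the interval bound nearest to 1. Which of these genes to print was chosen after their values were seen. Values of genes that also lead the cluster in which they are compared were marked, since clusters were made from them, and the genes whose spread over clusters is described were chosen after their values were seen.

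For 20 gene lists, the median log2 ratio of members with at least 20 UMIs over both libraries was computed with 0.5 UMI added, and set against 10000 random lists of the same size drawn from 20 bins of mean expression. The percentile places the list among the random ones. Genes within a list are not independent, so it is no test of the genotype.

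A second clustering used scanpy 1.11.5 with leidenalg 0.10.2 (2000 variable genes, 30 components, 15 neighbours, resolution 1) and gave 25 clusters. A further one left out 38 leading genes that differ over 2-fold between the libraries within their cluster and gave 24. Both used both libraries without integration. To compare depths, each cell was thinned to 769 UMIs, the 10th percentile, which left out 473 wild-type and 518 mutant cells. Proliferating cells were those with at least 2 of 8 cell cycle genes after thinning. Scrublet, with an expected rate of 0.06, marked 0 cells and so did not work as a doublet check. In its place, cells over the 98th percentile of UMIs were left out, 95 wild-type and 105 mutant, and, as a later addition, the 317 and 348 cells with the highest scores. A stricter choice of cells, with at least 1000 UMIs, at least 500 genes and under 10% mitochondrial UMIs, kept 2490 and 2682 cells.

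Other alternatives were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors on genes with at least 20 UMIs, totals without the 50 genes with most UMIs, the mean over cells of each cell's CPM, and thinned cells. Absorptive cells were also taken with the same weights for both classes and from both of these clusterings. Lists were also run with no minimum, with at least 100 UMIs, with means, over all cells, and without markers of pancreas, liver and blood. Alternatives added after the data were seen are named where their effect is given. The ratios of 1 further gene are not reported here, and the counts of genes and ratios leave it out.

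The steps were tested on simulated data, with Poisson counts drawn at the depth of each library from the pooled levels of both and known genes altered. Of genes with at least 50 CPM in absorptive cells, 62 of 66 altered by 1.5-fold, 79 of 79 altered by 2-fold and 55 of 55 altered by 4-fold had intervals on the right side of 1, and 95.5% of intervals of unaltered genes held the true ratio. Of 200 unaltered lists, 3.5% fell outside 95% of random lists. The simulated counts held no variation between cells beyond counting, as the intervals assume. They therefore do not show how well the intervals cover real cells. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3. No doublet removal, correction for free RNA or trajectory was computed.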

Results

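Single-cell RNA sequencing was done on intestinal epithelial cells of zebrafish larvae at 6 days after fertilisation. The cells carried a cldn15la-GFP reporter, which marks the gut epithelium, and were sorted as GFP-positive and 7-AAD-negative from pools of 600 to 700 larvae. The data held 2 libraries, fxr wild type and fxr mutant, with 1 library per genotype. The mutated gene, nr1h4, encodes Fxr, the nuclear receptor that senses bile acids, and the comparison asked how intestinal cells differed without it. The wild-type library held 4710 cells and 21975754 UMIs, with a median of 2680 UMIs and 761 genes per cell. The mutant library held 5208 cells and 29870229 UMIs, with a median of 3549 UMIs and 888 genes per cell. The median share of mitochondrially encoded UMIs was 5.42% in wild-type and 5.88% in mutant cells. With no replicates, no difference could be tested, so all values describe these 2 libraries only. Ratios are mutant over wild-type counts scaled to 1000000 UMIs (CPM), followed in brackets by a 95% interval that covers counting error only.

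The 27 deposited clusters carried numbers and no names, and marker genes fixed before the data were examined named 20 of them. Cluster 4 was enterocyte-like, with 235 wild-type and 458 mutant cells. Cluster 17, with 60 and 58 cells, carried markers of both ileocytes, the bile-salt-absorbing cells, and lysosome-rich enterocytes, which take up protein. These clusters together made up the absorptive cells, 295 wild-type and 516 mutant. Clusters 0, 2 and 15 were like best4/otop2 cells, an ion-transporting type, 3 and 14 like goblet cells, and 8, 11, 12, 21 and 22 like enteroendocrine cells. Cluster 13 was tuft-like and cluster 16 cycling. Cells of the 7 unnamed clusters made up 35.3% of the wild-type and 35.9% of the mutant library.

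nr1h4 was scarce in both libraries and its level was lower in the mutant one. Over all cells it had 155 wild-type UMIs, or 7.05 CPM [5.99 to 8.26], and 139 mutant UMIs, or 4.65 CPM [3.91 to 5.49], a ratio of 0.660 [0.521 to 0.835]. When every cell had equal weight the ratio was 0.936. In absorptive cells nr1h4 was at 22.6 CPM in the wild-type and 7.84 CPM in the mutant library, a ratio of 0.346 [0.201 to 0.590], from 36 and 26 UMIs. With all cells thinned to one depth this ratio was 0.942, and among cells with at least 1000 UMIs, at least 500 genes and under 10% mitochondrial UMIs, here called the stricter cells, it was 0.112. Both rest on fewer UMIs than the 36 and 26 above. Cells with an nr1h4 UMI made up 2.65% of the wild-type and 2.55% of the mutant library, and 0.637% and 0.448% after thinning. In unnamed cluster 6, with median depths of 12629 and 14839 UMIs, no nr1h4 UMI was detected, with exact upper limits of 1.38% and 0.969% for the share of cells with a detected UMI, which do not limit how many cells express the gene. In cluster 17 the ratio was 0.682 [0.327 to 1.39]. Its values there of 3.16 after thinning and 0.223 among the stricter cells, 11 wild-type and 7 mutant, rest on few UMIs. A 3′ tag does not show whether the transcript was intact, so these levels do not check the genotype.

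Most genes of bile salt uptake, binding and synthesis were lower in absorptive cells of the mutant library. fabp6, the ileal bile acid binding protein, was at 2176 CPM in the wild-type and 191 CPM in the mutant library, a ratio of 0.0878 [0.0805 to 0.0956]. cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 73 and 8 UMIs, a ratio of 0.0526 [0.0219 to 0.109], all of them in cluster 4. cyp8b1, a sterol hydroxylase of the same pathway, was at 0.210 [0.119 to 0.357], and slc10a2, the apical sodium-dependent bile acid transporter, at 0.204 [0.115 to 0.351]. In contrast, abcc2, an exporter of conjugated compounds, was higher in the mutant library at 1.29 [1.11 to 1.51], as was nr0b2a, which encodes the co-repressor Shp, at 1.57 [1.17 to 2.13]. The ratios of slc51a, a subunit of the organic solute transporter, slc27a2a, an acyl-CoA synthetase, and abcb4, a phospholipid transporter, were 0.465 [0.274 to 0.786], 0.440 [0.327 to 0.592] and 0.637 [0.459 to 0.888]. The hormone gene fgf19 had 3 wild-type UMIs and 0 mutant UMIs in absorptive cells, too few for a ratio. Of the 15 measured genes of Fxr and bile salt handling, 12 were below and 3 above a ratio of 1, with a median log2 ratio of -1.06. Relative to random gene lists matched for expression the median was -0.79, at percentile 0 of 10000 such lists. The percentile was 8.32 after thinning, 3.54 among the stricter cells and 8.01 with at least 100 UMIs per gene, each within the central 95% of random lists. With equal weight for every cell the ratios were 0.204 for fabp6, 0.127 for cyp7a1 and 0.374 for cyp8b1, and among the stricter cells 0.642 for slc10a2 and 0.728 for slc27a2a. Cluster 17 made up a larger part of the wild-type absorptive cells, and with the same class weights in both libraries fabp6 was at 0.169 and slc10a2 at 0.390.

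The fabp6 difference sat in cluster 17, which held 3442 of the 3464 wild-type fabp6 UMIs of absorptive cells; fabp6 is itself among the genes that lead this cluster. Its level there was 9560 CPM in the wild-type and 1483 CPM in the mutant library, a ratio of 0.155 [0.142 to 0.170]. With equal weight for every cell this ratio was 0.356, and among the stricter cells, only 11 wild-type and 7 mutant, it was 0.0506. In cluster 17, 61.7% of wild-type and 50.0% of mutant cells held a fabp6 UMI, and 54.2% and 42.9% did after thinning. In enteroendocrine-like cluster 11, not an absorptive type, these shares were 1.98% and 4.71%, and 0% and 1.67% after thinning; median depths were 4152 and 5120 UMIs in cluster 17, against 6392 and 6202 in cluster 11. In cluster 4, fabp6 had 22 and 75 UMIs, a ratio of 1.43 [0.878 to 2.41]. slc10a2 in cluster 17 was at 0.403 [0.223 to 0.704], and at 1.27 among these few stricter cells. slc51a was at 0.374 [0.152 to 0.839] in cluster 17 and at 1.02 in cluster 4. After thinning its ratios in absorptive cells and in cluster 17 were 1.41 and 3.16, on too few UMIs to show a reversal. abcc2 was at 1.60 [1.12 to 2.33] in cluster 17 but at 0.790 after thinning, and its ratio in absorptive cells was 0.994 with equal weight for every cell and 0.860 after thinning. nr0b2a went the other way in unnamed cluster 6, at 0.503 [0.445 to 0.569], and over all cells, at 0.825 [0.766 to 0.889]. In absorptive cells taken from clusters made without genes that differ between the libraries it was at 3.08.

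**Figure D1:**
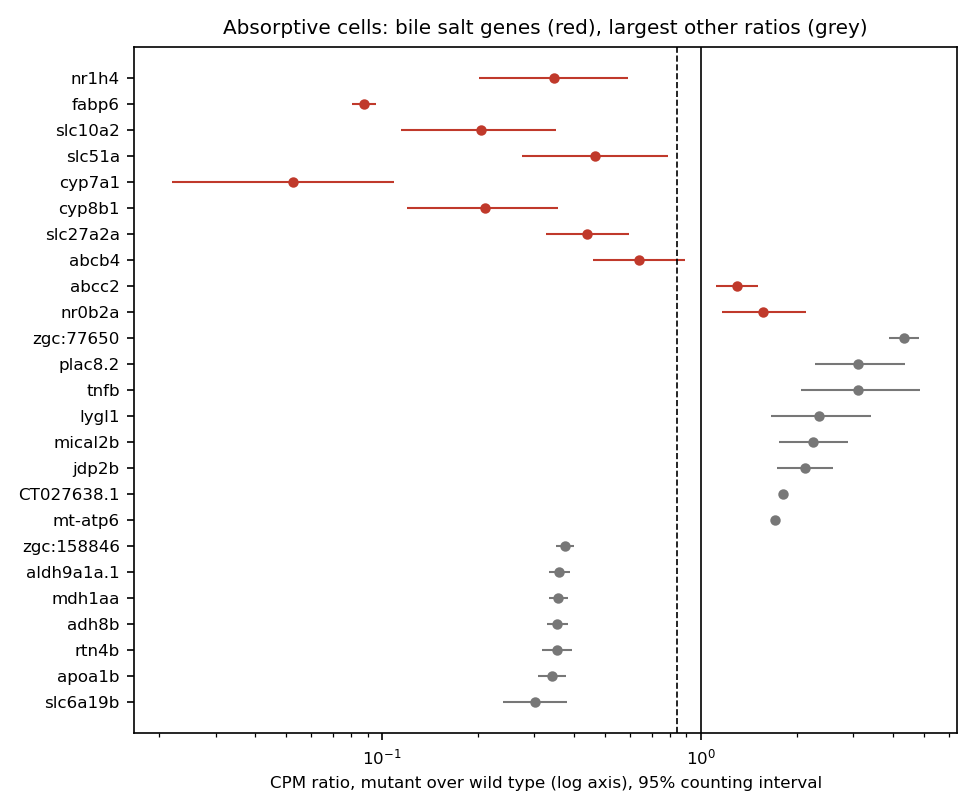
Ratio of CPM, mutant over wild type, of 25 genes in absorptive cells (log axis), 10 of bile salt handling in red and 15 others in grey; bars are exact 95% counting intervals and the dashed line marks the median gene at 0.839. fabp6 (0.0878) and cyp7a1 (0.0526) lie lowest and zgc:77650 (4.33) highest.

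Beyond bile salt handling, the genes furthest above 1 in absorptive cells of the mutant library included immune and mitochondrial genes, and those furthest below 1 included apolipoprotein and dehydrogenase genes, with hormone genes at both ends. The median gene of absorptive cells had a ratio of 0.839, a log2 ratio of -0.25, which other scalings moved by 0.31 (TMM), 0.24 (DESeq2) and 0.32 (totals without the 50 top genes). Ratios relative to the median gene are therefore also given. The uncharacterised gene zgc:77650 was at 234 CPM in the wild-type and 1016 CPM in the mutant library, 4.33 [3.89 to 4.84], or 5.17 relative to the median gene. tnfb, a tumour necrosis factor, was at 3.11 [2.06 to 4.85], relative 3.71, and lygl1, a g-type lysozyme, at 2.35 [1.66 to 3.41], relative 2.80. plac8.2 was at 3.12 [2.28 to 4.35], mical2b, an actin-modifying monooxygenase, at 2.25 [1.76 to 2.90], and jdp2b, a Jun dimerization protein, at 2.12 [1.73 to 2.60]. The mitochondrial transcripts mt-atp6 and mt-cyb were at 1.71 [1.68 to 1.74] and 1.66 [1.63 to 1.69]. Among the stricter cells they were at 2.46 and 2.31, and with equal weight for every cell at 1.34 and 1.29. In clusters made without genes that differ between the libraries mt-cyb was at 1.14. mt-atp6 was higher in 21 of the 23 clusters measured, so its rise was not particular to absorptive cells. CT027638.1, which has no description, alone made up 101168 CPM in the wild-type and 182859 CPM in the mutant library, a ratio of 1.81 [1.80 to 1.82], which was 3.47 among the stricter cells and 1.37 with equal weight for every cell. In cluster 17 it was at 0.237 [0.227 to 0.248], at 0.436 among the 11 wild-type and 7 mutant stricter cells and at 0.131 without the 6% of cells with the highest doublet scores.

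Among the lowest, the apolipoprotein genes apoa2 and apoa1b were at 0.236 [0.181 to 0.306] and 0.340 [0.308 to 0.376], or 0.281 and 0.406 relative to the median gene; apoa1b was at 0.219 after thinning and 0.556 among the stricter cells. slc6a19b, a neutral amino acid transporter, was at 0.302 [0.238 to 0.380]. mdh1aa, a cytosolic malate dehydrogenase, was at 0.356 [0.333 to 0.381], adh8b, an alcohol dehydrogenase, at 0.355 [0.328 to 0.383] and aldh9a1a.1, an aldehyde dehydrogenase, at 0.359 [0.334 to 0.387]. rtn4b, a reticulon, and zgc:158846 were at 0.353 [0.316 to 0.393] and 0.375 [0.352 to 0.400]. In cluster 4 alone, mdh1aa and apoa1b were both at 0.299, with intervals [0.278 to 0.321] and [0.271 to 0.331], and si:ch211-153b23.5 was at 3.84 [3.09 to 4.82], at 10.5 among the stricter cells and at 2.44 with equal weight for every cell; apoa1b is among the genes that lead this cluster. In cluster 17, mdh1aa turned to 1.11, and adh8b, aldh9a1a.1 and zgc:158846 were at 0.716, 0.846 and 0.888, while plin2, a lipid droplet coat protein, was at 0.200 [0.0857 to 0.416] and wu:fi09b08 at 0.0746 [0.0234 to 0.183], and at 0.186 among the stricter cells. Of the 24 genes of the most extreme ratios in absorptive cells, 7 moved by over 1.5 times without their 2 highest cells per library. These were BX908782.2, from 13.8 to 28.7, penka, from 6.89 to 2.69, pyyb, from 2.54 to 1.33, mlnl, from 2.06 to 0.978, insl5a, from 0.0426 to 0.424, galn, from 0.0589 to 0.839, and c2cd4a, from 0.177 to 3.60. In clusters made without genes that differ between the libraries, jdp2b turned to 0.630, tnfb was at 1.51 and lygl1 at 1.39, while among the stricter cells tnfb was at 17.3, lygl1 at 12.4 and plac8.2 at 7.94. Equal weight for every cell took mical2b to 1.22 and plac8.2 to 1.95.

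Most lists of metabolic and absorptive genes lay below their random lists in absorptive cells. Members are counted against the median of the random lists. Fatty acid oxidation had 21 of 27 measured members below it, with a median log2 ratio of -0.75, or -0.50 relative to random lists (percentile 0). With equal weight for every cell and after thinning it was at -0.23 and -0.35, at percentiles 4.615 and 3.91, within 95% of random lists; hadh and hadhb, enzymes of beta oxidation, were at 0.407 [0.312 to 0.531] and 0.465 [0.348 to 0.622]. Glycolysis and gluconeogenesis had 15 of 21 below, a median of -0.75 and a relative median of -0.49 (percentile 0.02), with fbp1b, a fructose bisphosphatase, at 0.421 [0.363 to 0.487]. Lipoprotein and dietary lipid absorption had 17 of 27 below, a median of -0.62 and a relative median of -0.34 (percentile 0.200), although apoa4a, an apolipoprotein, was at 2.14 [1.52 to 3.08]. It came to lie within 95% of random lists with no minimum of counts (-0.22, percentile 4.29), without markers of pancreas, liver and blood (-0.22, percentile 2.65) and without the 2 highest cells per gene (-0.15, percentile 9.335). Brush border digestion and nutrient transport had 26 of 32 below, a median of -0.60 and a relative median of -0.33 (percentile 0.150); chia.2, a chitinase that also leads cluster 4, was at 0.477 [0.463 to 0.492]. Cholesterol synthesis and uptake had 18 of 25 below, a median of -0.60 and a relative median of -0.37 (percentile 0.220), with the synthesis enzymes cyp51 and msmo1 at 0.313 [0.241 to 0.406] and 0.420 [0.347 to 0.507] and insig1, a brake on synthesis, at 1.32 [1.04 to 1.68]. With equal weight for every cell this list was at -0.30 (percentile 2.945), within 95% of random lists, and cyp51 at 0.193; insig1 was at 3.07 after thinning and at 2.16 in clusters made without genes that differ. Xenobiotic and redox metabolism had 27 of 43 below, a median of -0.49 and a relative median of -0.22 (percentile 1.34), but lay within 95% among the stricter cells (percentile 3.73), after thinning (percentile 10.72) and with means (percentile 3.56), with the peroxidase gene gpx1a at 0.458 [0.391 to 0.536] and the peroxiredoxin gene prdx1 at 1.45 [1.22 to 1.75]. Ion and acid-base transport had 15 of 24 below, a median of -0.54 and a relative median of -0.30 (percentile 1.28), but lay within 95% with equal weight for every cell (percentile 8.99), among the stricter cells (percentile 10.36) and with other minimums of counts or means, with the water channel gene aqp8a.2 at 0.422 [0.364 to 0.489]. Proliferation had 16 of 26 below, a median of -0.74 and a relative median of -0.47 (percentile 0.0400), but turned to 0.20 after thinning (percentile 76.86) and was at -0.071 with at least 100 UMIs per gene (percentile 36.975), with pcna, a replication clamp, at 0.395 [0.311 to 0.501]. Retinoid and carotenoid handling had 12 of 13 below, a median of -0.62 and a relative median of -0.35, at percentile 3.16, within the central 95% of random lists, but lay below it in cluster 4 (percentile 0.15), with the same class weights (percentile 0.225), with other minimums of counts or means, and without the highest doublet scores or the 2 highest cells per gene; rdh1, a retinol dehydrogenase, was at 0.492 [0.393 to 0.616].

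The absorptive cells of the libraries also differed in their makeup. Among enterocyte-like cells the median share of mitochondrial UMIs was 9.67% in the wild-type and 13.7% in the mutant library. When cells were clustered without the genes that differ between the libraries, 52 of 237 wild-type and 23 of 518 mutant enterocyte-like cells fell in a cluster led by pck1, chia.2 and cd36. The absorptive cells of that clustering also took in a wider ileocyte- and lysosome-rich-like group of 333 wild-type and 224 mutant cells, so that both parts changed at once. These cells were most often of unnamed cluster 9. Of its markers over 2-fold, cluster 9 had 0 of 5 for ileocytes, 0 of 10 for lysosome-rich and 0 of 12 for other enterocytes. Markers thus do not show cluster 9 to be absorptive. In these wider absorptive cells the relative medians of lipid absorption, brush border, xenobiotic metabolism and proliferation turned to 0.031, 0.027, 0.13 and 0.46, and cholesterol synthesis and glycolysis were at -0.090 and -0.21, within 95% of random lists. The second clustering kept the differing genes and took in a like group of 327 and 217 cells. Lipid absorption, brush border, xenobiotic metabolism and proliferation also turned there, so leaving those genes out was not needed for it. Fatty acid oxidation was at 0.37 in cluster 17 (percentile 97.435, within 95% of random lists), with 16 of 16 measured members above the random median. There hadh, hadhb, fbp1b, rdh1 and uqcrc2a, a subunit of complex III, turned to 1.18, 1.67, 1.26, 1.07 and 1.25, chia.2 to 2.44 and prdx1 to 0.716. In cluster 17, cholesterol synthesis, glycolysis and ion transport were at 0.0071, 0.055 and 0.20, within 95% of random lists. Only 4, 15 and 10 of their members were measured there, against 25, 21 and 24 in absorptive cells.

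Mitochondrially encoded and immune genes were the lists furthest above their random lists in absorptive cells. Over all cells the mitochondrially encoded list also lay above its random lists, at 0.34 relative to them (percentile 100). In absorptive cells all 13 mitochondrially encoded genes were above the median of their random lists, with a median log2 ratio of 0.61, or 0.88 relative to random lists (percentile 100). Immune and inflammatory genes had 20 of 23 members above it, a median of 0.27 and a relative median of 0.49 (percentile 100), which was 0.12 after thinning (percentile 72.9). isg15, an interferon-stimulated gene, went the other way at 0.505 [0.378 to 0.674], yet was at 2.23 in cluster 17. Nuclear genes of oxidative phosphorylation had 32 of 53 above it, a median of -0.08 and a relative median of 0.18 (percentile 99.6), but lay within 95% of random lists under many choices of cells, at 0.027 among the stricter cells (percentile 63.89), 0.030 with the same class weights (percentile 70.26) and 0.094 in cluster 4 (percentile 86.75). In absorptive cells cox8a, a subunit of cytochrome oxidase, was at 1.46 [1.27 to 1.68], and at 0.941 in clusters made without genes that differ, and uqcrc2a was at 0.440 [0.373 to 0.520].

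The other lists lay within 95% of their random lists in absorptive cells. Transcription factors of gut identity had 22 of 30 members above the random median, a median of -0.04 and a relative median of 0.20 (percentile 97.3), but lay above 95% of random lists among the stricter cells (percentile 97.86), with the same class weights (percentile 99.46), in cluster 4 (percentile 99.4), in a second clustering (percentile 99.555), with other minimums of counts or means and without the 2 highest cells per gene, with klf3 at 1.56 [1.21 to 2.04] and cebpa at 0.425 [0.344 to 0.525]. Dissociation and immediate early genes had 24 of 42 above, a median of -0.19 and a relative median of 0.068 (percentile 77.9), but 0.43 in cluster 4 and 0.77 among the stricter cells, both at percentile 100, and -0.17 in clusters made without genes that differ (percentile 1.64); egr1, an immediate early factor, was at 0.452 [0.348 to 0.588] and fosb at 1.32 [1.06 to 1.65]. egr1 turned to 1.15 among the stricter cells and fosb to 0.748 in clusters made without genes that differ. Endoplasmic reticulum stress and secretion had 20 of 36 above, a median of -0.23 and a relative median of 0.031 (percentile 62.4), which was 0.31 in cluster 4 (percentile 99.7) and -0.32 in cluster 17 (percentile 0.06). Endocytosis and lysosome genes had 21 of 37 below, a median of -0.26 and a relative median of -0.0064 (percentile 46.6); pllp, a protein of endosomes, was at 0.425 [0.322 to 0.560]. Ribosomal protein genes had 44 of 88 below and 44 above, and a median of -0.27 (percentile 50.3). The enteroendocrine list, with 15 measured members, had a median of -0.0056 (percentile 85.6) but lay above 95% of random lists after thinning (percentile 99.98) and below with no minimum of counts (percentile 2.2), and the mucus list, with 3, one of -0.11 (percentile 70). In their own cells, the enteroendocrine list had a median of -0.09 over 36 members of enteroendocrine-like cells (percentile 6.14), and the mucus list one of 0.07 over 6 members in goblet-like cells (percentile 87.3).

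**Figure D2:**
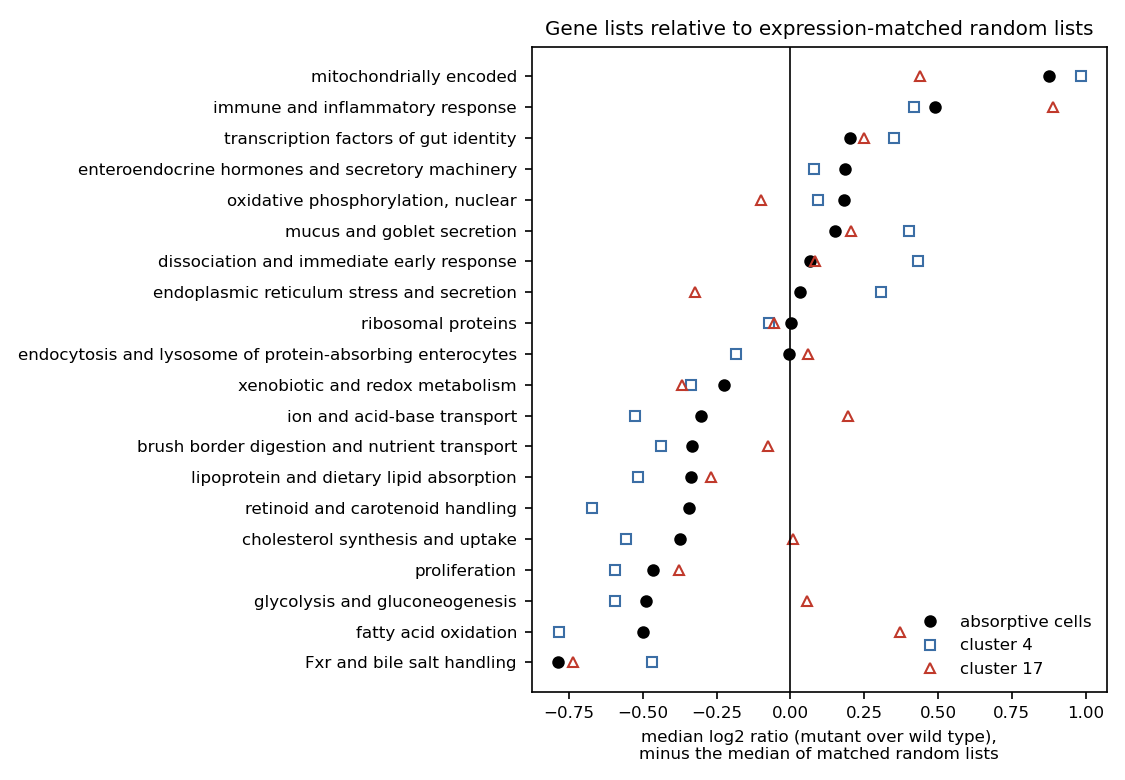
Median log2 ratio of each of the 20 gene lists minus the median of its matched random lists, in absorptive cells, in cluster 4 and in cluster 17. Fxr and bile salt handling is lowest in absorptive cells (-0.79), mitochondrially encoded genes highest (0.88), and fatty acid oxidation lies on opposite sides in absorptive cells (-0.50) and in cluster 17 (0.37, percentile 97.435).

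Cell types differed in their shares between the libraries, with more enterocyte-like and fewer tuft-like cells in the mutant one. Shares are from clusters made without the leading genes that differ between the libraries, except for tuft-like cells and numbered clusters. Enterocyte-like cells made up 5.03% [4.42 to 5.70] of wild-type and 9.95% [9.15 to 10.8] of mutant cells, a ratio of 1.98 [1.69 to 2.31]. In the deposited clusters this ratio was 1.76 [1.50 to 2.07]. More of the deposited enterocyte-like cells of the mutant library had at least 10% mitochondrial UMIs, 69.0% against 48.9%. With such cells and shallow cells left out the ratio was 1.14 [0.857 to 1.51], and 0.990 [0.735 to 1.34] in the deposited clusters. Tuft-like cells, the chemosensory type, were 3.72% of wild-type and 2.19% of mutant cells in the deposited clusters, a ratio of 0.589 [0.461 to 0.750]. Enteroendocrine-like cells were 16.5% and 13.8%, a ratio of 0.833 [0.752 to 0.924]. A cluster among these, with 159 wild-type and 136 mutant cells, was most often of unnamed cluster 5. Cluster 5 had 0 of 21 enteroendocrine markers over 2-fold. In the deposited clusters enteroendocrine-like cells were 14.6% and 12.8%, a ratio of 0.877 [0.787 to 0.977]. Goblet-like cells were 11.8% and 10.1%, or 0.851 [0.754 to 0.960]. The goblet ratio turned to 1.03 among the stricter cells, and 43.4% of wild-type against 28.3% of mutant goblet-like cells had under 1000 UMIs. The best4/otop2-like share was 23.7% and 22.4%, a ratio of 0.944 [0.869 to 1.03]. Within it, cluster 15, led by hsp70 genes, was at 0.335 [0.249 to 0.447], with 178 and 66 cells, and cluster 2 at 1.22 [1.06 to 1.404].

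Rarer groups were counted with less precision. Cluster 17 held 1.27% of wild-type and 1.11% of mutant cells, a ratio of 0.874 [0.599 to 1.28]. The wider ileocyte- and lysosome-rich-like group of the other clustering, which took in unnamed cluster 9, was at 0.608 [0.511 to 0.723]. Cluster 9 alone was at 0.567 [0.462 to 0.695], with 0 of 5 ileocyte and 0 of 10 lysosome-rich markers over 2-fold. The 0.608 is therefore no share of ileocytes or lysosome-rich cells alone. The wider group was at 0.928 [0.505 to 1.71] among the stricter cells and at 1.14 [0.697 to 1.88] with the mitochondrial limit alone, which left 32 and 39 of its 333 and 224 cells. Exocrine pancreas-like cells had a ratio of 0.884 [0.567 to 1.38]. Epidermis-like cells were at 1.51 [1.07 to 2.13], and at 0.986 in the deposited clusters with only cells of at least 1000 UMIs and 500 genes. Erythroid-like cells, with 7 and 32 cells, were at 4.13 [1.79 to 11.1], and at 12.998 [1.98 to 550] among the stricter cells, with 1 and 14 cells. Cluster 18 was at 1.56 [1.05 to 2.32], with median depths of 9760 and 2140 UMIs, and cluster 19 at 0.703. Cycling cluster 16 held 32 wild-type and 91 mutant cells, a ratio of 2.57 [1.70 to 3.98], which was 1.80 [0.975 to 3.45] among the stricter cells. Proliferating cells over all clusters, with UMIs of at least 2 of 8 cell cycle genes after thinning, were 8 of 4237 wild-type and 6 of 4690 mutant cells, 0.189% [0.0816 to 0.372] and 0.128% [0.0470 to 0.278]. Their ratio was 0.678 [0.194 to 2.23] at this depth, with an interval on both sides of 1, and 1.39 [0.969 to 2.01] without thinning. Unnamed cluster 1 was at 1.61 [1.39 to 1.86] and cluster 7 at 0.429 [0.357 to 0.515], while both together were at 0.948 [0.851 to 1.06].

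**Figure D3:**
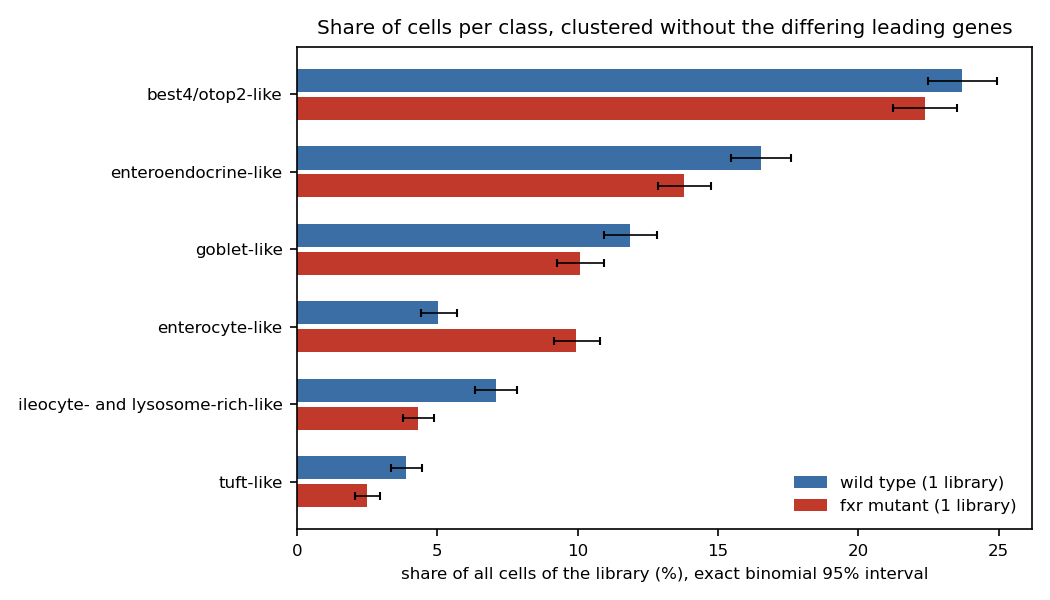
Percent of the cells of each library in 6 cell classes, from the clustering made without genes that differ between the libraries; bars are exact binomial 95% intervals. Enterocyte-like cells made up 5.03% of the wild-type and 9.95% of the mutant library.

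In the other clusters, mt2, a metal-binding metallothionein, was lower in the mutant library across unrelated cell types, and heat shock genes went both ways. mt2 was lower in 13 and higher in 2 of the 21 clusters measured, at 0.163 [0.135 to 0.194] in enteroendocrine-like cluster 8, 0.255 [0.190 to 0.339] in best4/otop2-like cluster 0 (0.0854 among the stricter cells) and 0.144 [0.118 to 0.174] in unnamed cluster 1. zgc:77650 was higher in 21 of 23 clusters, at 2.11 [1.83 to 2.42] and 1.96 [1.73 to 2.24] in goblet-like clusters 3 and 14. The heat shock gene hsp70.2 was at 0.280 [0.239 to 0.329] in best4/otop2-like cluster 2, at 3.37 [2.72 to 4.19] in tuft-like cluster 13 and at 4.09 [2.90 to 5.83] in unnamed cluster 7. In cluster 13 it was at 11.3 without the cells with the highest doublet scores, and in cluster 7 at 2.28 with equal weight for every cell. hspa5, the endoplasmic reticulum chaperone BiP, was at 1.95 [1.85 to 2.05] in cluster 2 and higher in 13 of 23 clusters. fabp6 was lower in 6 and higher in 6 of 20 clusters, at 0.152 [0.101 to 0.221] in goblet-like cluster 3, from 212 and 32 UMIs, and at 1.48 [1.32 to 1.65] in cluster 2. In cluster 8 it was at 1.60 [1.35 to 1.89], and at 1.03 after thinning.

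The most extreme ratios of these clusters also included genes of other functions, some of them in several clusters. In best4/otop2-like cluster 0, cpne2, a copine, was at 3.50 [2.299 to 5.49] and si:dkeyp-4c4.2 at 0.0837 [0.0421 to 0.152]. In cluster 15, the stress gene gadd45bb was at 0.182 [0.102 to 0.301]. In goblet-like cluster 3, tiparp, a target of the aryl hydrocarbon receptor, was at 2.13 [1.79 to 2.54], and the aminopeptidase gene anpepa at 0.497 [0.379 to 0.647]. In goblet-like cluster 14, prdx1 was at 2.63 [1.86 to 3.80], and at 1.58 with equal weight for every cell. In enteroendocrine-like clusters, the galanin gene galn was at 2.74 [2.57 to 2.93] in cluster 8, igfbp1a, an insulin-like growth factor binding protein, at 2.18 [1.99 to 2.38] in cluster 11, and rgs16, a regulator of G-protein signalling, at 0.504 [0.437 to 0.580] in cluster 12. The transcobalamin gene tcnba, for a vitamin carrier, was at 2.25 [2.104 to 2.41] in unnamed cluster 6 and at 0.459 [0.417 to 0.504] in cluster 11, where it turned to 2.12 without the cells with the highest doublet scores. In cluster 6, equal weight for every cell took tcnba to 1.21, and leaving out the highest doublet scores took it to 4.26. In unnamed cluster 10, jdp2b and tnfb were at 2.67 [2.32 to 3.09] and 2.62 [2.14 to 3.22]. All 10 genes of exocrine pancreas-like cluster 20 with the most extreme ratios moved by over 1.5 times without their 2 highest cells, as did 7 of 10 in cluster 13 and 6 of 10 in each of clusters 5 and 12.

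**Figure D4:**
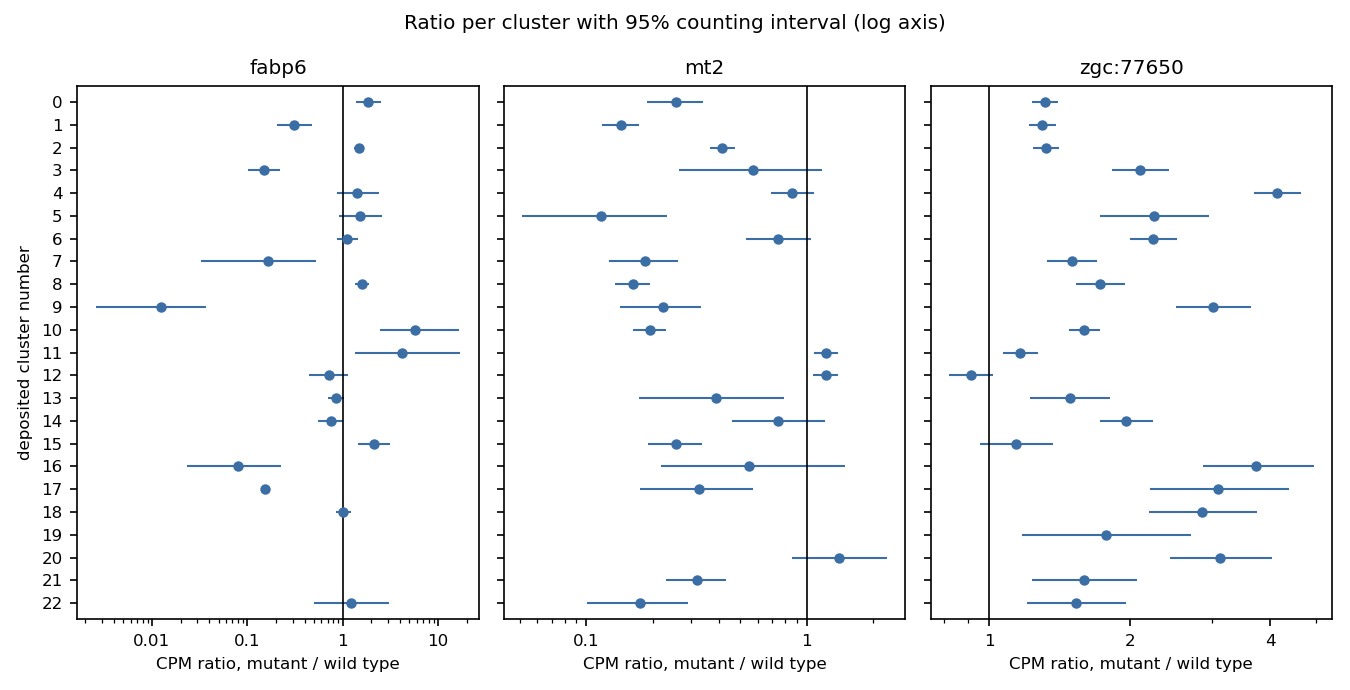
Ratio of CPM, mutant over wild type, of fabp6, mt2 and zgc:77650 in each deposited cluster with enough cells (log axis). fabp6 lies on both sides of 1, mt2 is below 1 in most clusters and zgc:77650 above 1 in 21 of 23.

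Summed over all cells, which mixes levels with cell shares, tnfb was at 2.08 [1.91 to 2.28], CT027638.1 at 2.06 [2.05 to 2.07] and zgc:77650 at 1.64 [1.60 to 1.68] in the mutant library. The enterocyte genes fabp1b.1, a fatty acid binding protein, and afp4.1 were at 1.80 [1.76 to 1.84] and 1.74 [1.64 to 1.86]; both lead enterocyte-like cluster 4, and among the stricter cells they were at 0.772 and 1.07. fabp6 was at 0.401 [0.384 to 0.419] and mt2 at 0.370 [0.353 to 0.387]. nutf2, a nuclear transport factor, was at 0.412 [0.374 to 0.454]. si:ch211-270g19.5 and si:dkey-61f9.1, which lead tuft-like cluster 13, were at 0.348 [0.320 to 0.378] and 0.417 [0.399 to 0.437]. The enteroendocrine list had 36 of 38 members below the median of its random lists over all cells, with a median log2 ratio of -0.52 (percentile 0). Hormone genes rested on few cells: pomca, the precursor of melanocortins, was at 77.4 and at 1.47 without its 2 highest cells per library, sst1.2, a somatostatin gene, at 0.0428 and 0.663, sst2 at 0.217 and 0.461, and gip at 0.225 and 1.08.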

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

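Of the tests weighed here, that of damaged cells was set before its value was seen; those of free RNA, of a few cells, of fewer ileocytes, of sequencing depth, of differing genes and of dissociation stress were chosen only after the results were seen.

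The first pattern is fabp6, lower in the mutant library in cluster 17 and higher in clusters 2 and 8, although thinning took its ratios in clusters 2 and 8 to 1.24 and 1.03. Free fabp6 RNA, which would add alike UMIs to every cell, is argued against for the higher levels without thinning, since the mutant library held 0.666 and 0.651 more fabp6 UMIs per cell in clusters 2 and 8, or 0.408 and 0.327 at the bounds of the counting intervals, while mutant cells of enteroendocrine-like cluster 11 held 0.0838 [0.0479 to 0.136] in all. A few cells with many UMIs are argued against too, since without the 2 highest cells per library the ratio in cluster 17 was 0.184 [0.165 to 0.205] and the intervals of clusters 2 and 8 stayed above 1. The summed UMIs of the other ileocyte markers had a ratio of 0.566 [0.388 to 0.819] in cluster 17, above the 0.155 [0.142 to 0.170] of fabp6. That sum was raised by slc13a1, which had 0 wild-type and 11 mutant UMIs, and ccl25b had none. slc10a2 and tmigd1 were at 0.403 [0.223 to 0.704] and 0.478 [0.255 to 0.863]. The fabp6 ratio with equal weight for every cell, given above, lies within both of these intervals. Fewer ileocytes within cluster 17 therefore stay open. An effect of the genotype on fabp6 stays open as a hypothesis, as does any difference between the pools of larvae, since genotype and library are confounded.

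The second pattern is the larger share of enterocyte-like cells in the mutant library, which was 1.11 times the wild-type share in the deposited clusters where cells with at least 10% mitochondrial UMIs were left out. Damaged cells that kept mitochondrial RNA were predicted to hold fewer UMIs. Mutant enterocyte-like cells over that limit instead held more than those under it, with medians of 5874.5 and 3412.5. Their ratio was 1.72 [1.34 to 2.14], while the wild-type ratio was 1.02 [0.673 to 1.50]. Cells over and under the limit were not matched for type, so median depth does not show that they were intact. Damage therefore stays open. Among cells with at least 1000 UMIs and 500 genes the share ratio was 1.99 [1.66 to 2.38]. That minimum does not bring the libraries to one depth, and shares were not computed on thinned cells. Deeper sequencing therefore stays open. The 38 leading genes that differ between the libraries are argued against as what set the clusters, since without them the share ratio was 1.98 [1.69 to 2.31]. Other differing genes stayed in. CT027638.1, at 2.06 over all cells, was among the genes that led the larger enterocyte-like cluster there. Clusters set by such genes therefore stay open. The genotype stays open, as do sorting and handling of the pools, which were not tested.

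The third pattern is mt2, lower in the mutant library in 13 of 21 clusters. Free mt2 RNA is argued against outside cluster 13, since mt2 fell by at least 0.247 UMIs per cell in each of the other 12 clusters, or 0.149 at the bounds of the counting intervals, while wild-type cells of goblet-like cluster 3 held 0.0552 [0.0350 to 0.0828] in all. In cluster 13, where the fall was 0.141 UMIs per cell and 0.00198 at the bounds, free RNA cannot be told apart from a lower level because of the few counts. Argued against are also a few cells with many UMIs, since 14 clusters were lower without the 2 highest cells per library. A weaker dissociation stress in the mutant library cannot be told apart from an effect of the genotype over all 13 clusters, since the immediate early list lay below 95% of its random lists in 4 of them, too few for the one reading and too many for the other. In clusters 7, 10 and 13 the list lay at least 0.27 (log2) above its random lists, at percentiles of 99.955 or more. These clusters were picked because the list was high there, so no conclusion on dissociation stress is drawn from them. The genotype stays open and was not tested apart from the library.

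Of 104 genes checked in 18 clusters, 17 had ratios over 1.5-fold above 1 in a cluster and over 1.5-fold below 1 in another, also without the 2 highest cells per library, with at least 100 CPM. These differences between clusters were not tested. For each gene, the higher and the lower ratio whose interval bound nearest to 1 lay furthest from 1 follow. CT027638.1 was at 3.54 in cluster 8 and 0.237 in cluster 17. abcc2 was at 1.60 in cluster 17 and 0.411 in cluster 15. aldh9a1a.1 was at 1.53 in cluster 9 and 0.305 in cluster 4. chia.2 was at 1.75 in cluster 5 and 0.234 in cluster 7. ctsl.1, a cathepsin gene that also leads cluster 17, was at 1.79 in cluster 17 and 0.402 in cluster 20. fabp1b.1 was at 27.3 in cluster 10 and 0.444 in cluster 7, and fabp6 at 1.87 in cluster 0 and 0.0125 in cluster 9. galn was at 2.74 in cluster 8 and 0.652 in cluster 5. The heat shock genes hsp70.1 and hsp70.2 were at 14.3 and 12.8 in cluster 20 and at 0.286 and 0.280 in cluster 2. hsp70l was at 6.13 in cluster 20 and 0.294 in cluster 0, and hsp70.3 at 4.98 in cluster 12 and 0.582 in cluster 1. icn was at 2.72 in cluster 15 and 0.566 in cluster 13, and id1, an inhibitor of DNA binding, at 2.16 in cluster 15 and 0.318 in cluster 7. pyyb was at 2.85 in cluster 12 and 0.166 in cluster 0. si:ch211-153b23.5 was at 3.84 in cluster 4 and 0.498 in cluster 14, and tcnba at 12.9 in cluster 20 and 0.459 in cluster 11. Some of these ratios moved by over 1.5 times without the 2 highest cells per library: CT027638.1 in cluster 8 to 1.91, ctsl.1 in cluster 17 to 2.76, fabp1b.1 in cluster 10 to 8.39, fabp6 in cluster 9 to 0.0501, hsp70l in cluster 20 to 10.5, pyyb in clusters 12 and 0 to 1.60 and 0.321, and tcnba in cluster 20 to 2.89. abcc2 in cluster 17 turned to 0.790 after thinning, fabp6 in cluster 0 to 0.832 among the stricter cells and tcnba in cluster 11 to 2.12 without the 6% of cells with the highest doublet scores.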

How the results depend on the processing

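The alternatives without the 2 highest cells per gene, without the highest doublet scores, with clusters made without differing genes, in cluster 4 or 17 alone, in a list's own cells, and with only one part of the stricter limits or with these together with other clusters were chosen after seeing the data; the others were set before. Of 1747 gene ratios under alternatives, over 151 results, 1109 stayed within the counting interval of the main ratio, 47 crossed 1 where that interval did not hold 1, and the other 591 left the interval. For shares of cell classes the main ratio was that of the deposited clusters, not of the clusters made without differing genes. Of 102 shares, over 13 results, 89 stayed within the interval of the main ratio, 5 crossed 1 in this sense and the other 8 left it. Moves of over 1.5 times were found for 75 of the 151 gene ratios under an alternative set before and for 96 under any. They were 55 of 150 among the stricter cells, 31 of 149 after thinning, 29 of 151 with equal weight for every cell and 0 with the other scalings. Those scalings multiply every ratio of a set by the same factor, so that 0 says nothing about single genes. Of 379 list medians, over 20 lists, 292 kept their place below, within or above the central 95% of random lists, 37 lost and 26 gained a place outside it, 19 changed side after lying outside it and 5 came to lie outside it on the other side. No paired analysis was possible because each genotype had 1 library, both numbered replicate 1. Cycling cells had no counterpart in the second clustering and so no share there. The depth limits nr1h4, with 155 and 139 UMIs over all cells. The cause was not tested for any of the differences below. Ratios are mutant over wild type, and list values are log2 medians relative to random lists. Bile salt handling, lipid absorption, brush border, cholesterol synthesis, fatty acid oxidation, glycolysis, xenobiotic metabolism, immune genes, proliferation, ion transport and oxidative phosphorylation lay outside 95% of random lists before these alternatives, and their values below lay within it, except that cholesterol synthesis and xenobiotic metabolism over all cells, and proliferation over all cells and in both other clusterings, lay above it. The other lists named below lay within it before, and their values below lay outside it.

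fabp6 was at 0.109 in absorptive cells and 0.137 in cluster 17 with TMM factors, at 0.104 in absorptive cells with DESeq2 size factors and at 0.110 without the 50 top genes. With equal weight for every cell, absorptive ratios were fabp6 0.204, abcc2 0.994 and ddit3 0.918, fabp6 in cluster 17 was at 0.356 and nr1h4 over all cells at 0.936; lists were cholesterol synthesis -0.30, fatty acid oxidation -0.23 and ion transport -0.20. In thinned cells, absorptive ratios were fabp6 0.122, slc51a 1.41, abcc2 0.860, hadhb 1.13 and ddit3 0.959, and those of cluster 17 fabp6 0.205, slc51a 3.16 and abcc2 0.790. The slc51a ratios rest on few UMIs. Lists in thinned cells were bile salt handling -0.37, fatty acid oxidation -0.35, xenobiotic metabolism -0.17, immune genes 0.12, proliferation 0.20 and enteroendocrine hormones 1.59.

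Among the stricter cells, absorptive ratios were fabp6 0.0286, pyyb 0.853, mlnl 0.827 and egr1 1.15, those of cluster 17 fabp6 0.0506 and slc10a2 1.27, and fabp1b.1 over all cells was at 0.772, fabp6 in cluster 0 at 0.832 and hsp70.2 in cluster 9 at 0.811. Only 11 wild-type and 7 mutant cells of cluster 17 were stricter cells. Share ratios of the deposited clusters were goblet-like 1.04, enterocyte-like 0.990, erythroid-like 12.998 and ileocyte- and lysosome-rich-like 0.591. Lists were bile salt handling -0.37, xenobiotic metabolism -0.17, immediate early genes 0.77, ion transport -0.17, oxidative phosphorylation 0.027 and gut transcription factors 0.34. With the UMI and gene minimum alone, share ratios were goblet-like 1.06, epidermis-like 0.986 and erythroid-like 11.8, and with the mitochondrial limit alone the enterocyte-like ratio was 1.11. The stricter cells in clusters made without differing genes gave goblet-like 1.03, enteroendocrine-like 0.782, enterocyte-like 1.14 and erythroid-like 12.998.

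Without cells over the 98th percentile of UMIs, fabp6 was at 0.126 in absorptive cells and 0.207 in cluster 17, and oxidative phosphorylation at 0.012. Without the 6% of cells with the highest doublet scores, fabp6 in cluster 17 was at 0.126, sst1.2 over all cells at 1.17 and tcnba in cluster 11 at 2.12; lists were retinoid handling -0.49, immediate early genes 0.16 and oxidative phosphorylation 0.14. Without the 2 highest cells per gene, absorptive ratios were fabp6 0.109, mlnl 0.978 and c2cd4a 3.60, fabp6 in cluster 17 was at 0.184 and gip over all cells at 1.08; lists were lipid absorption -0.15, retinoid handling -0.41 and gut transcription factors 0.27.

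With the same class weights in both libraries, fabp6 was at 0.169, and lists were retinoid handling -0.63, immediate early genes 0.23, oxidative phosphorylation 0.030 and gut transcription factors 0.29. In the second clustering, absorptive ratios were fabp6 0.101, jdp2b 0.637, rbp2a 1.03, fosb 0.835 and cox8a 0.925, the enterocyte-like share ratio was 2.07, and lists were lipid absorption 0.021, brush border 0.020, cholesterol synthesis -0.052, xenobiotic metabolism 0.13, proliferation 0.40, endoplasmic reticulum stress 0.25, oxidative phosphorylation 0.078 and gut transcription factors 0.26. In clusters made without differing genes, absorptive ratios were fabp6 0.101, jdp2b 0.630, c2cd4a 2.25, rbp2a 1.05, fosb 0.748 and cox8a 0.941. Lists were then lipid absorption 0.031, brush border 0.027, cholesterol synthesis -0.090, glycolysis -0.21, xenobiotic metabolism 0.13, proliferation 0.46, immediate early genes -0.17, endoplasmic reticulum stress 0.23, enteroendocrine hormones 0.45 and oxidative phosphorylation 0.075.

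In cluster 4 alone, fabp6 was at 1.43 and slc51a at 1.02, and lists were retinoid handling -0.67, immediate early genes 0.43, endoplasmic reticulum stress 0.31, oxidative phosphorylation 0.094 and gut transcription factors 0.35. In cluster 17 alone, ratios were fabp6 0.155, CT027638.1 0.237, pyyb 0.851, mlnl 0.281, mdh1aa 1.11, chia.2 2.44, hadh 1.18, hadhb 1.67, fbp1b 1.26, sult2st2 1.11, prdx1 0.716, rdh1 1.07, isg15 2.23, ddit3 0.970, atp1a1a.4 1.18, uqcrc2a 1.25 and rps27l 0.606. Lists there were lipid absorption -0.27, brush border -0.076, cholesterol synthesis 0.0071, fatty acid oxidation 0.37, glycolysis 0.055, proliferation -0.38, endoplasmic reticulum stress -0.32, ion transport 0.20 and oxidative phosphorylation -0.098.

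With no minimum of counts, lists were lipid absorption -0.22, retinoid handling -0.38, enteroendocrine hormones -0.37, ion transport -0.20 and gut transcription factors 0.23, and with at least 100 UMIs bile salt handling -0.39, retinoid handling -0.59, proliferation -0.071, ion transport -0.27 and gut transcription factors 0.23. With means in place of medians, lists were xenobiotic metabolism -0.16, retinoid handling -0.39, ion transport -0.10, oxidative phosphorylation 0.070 and gut transcription factors 0.22. Without markers of pancreas, liver and blood, lipid absorption was at -0.22. Over all cells, lists were bile salt handling -0.15, lipid absorption 0.057, brush border -0.050, endocytosis 0.18, cholesterol synthesis 0.19, glycolysis 0.048, xenobiotic metabolism 0.12, immune genes 0.079, proliferation 0.12, endoplasmic reticulum stress 0.13, enteroendocrine hormones -0.41, ion transport -0.038 and ribosomal proteins 0.12.

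Other gene ratios that left their counting interval and moved by over 1.5 times included the following. With equal weight for every cell these were penka at 2.22 and egr1 at 0.232 in absorptive cells; cyp7a1 at 0.114 in cluster 4; sst1.2 at 0.824, sst2 at 0.916, gip at 0.805 and pomca at 34.4 over all cells. Among the stricter cells these were slc51a at 0.843, jdp2b at 3.44, penka at 34.3, insl5a at 0.0165, galn at 0.0102 and klf3 at 2.91 in absorptive cells; slc51a at 0.955 and zgc:77650 at 8.91 in cluster 17; apoa1b at 0.508 and aldh9a1a.1 at 0.473 in cluster 4; sst1.2 at 0.0179 over all cells; si:dkey-28k24.2 at 0.191 and si:dkey-190j3.2 at 0.292 in cluster 0; fabp6 at 0.265 in cluster 3; mt2 at 0.0884 in cluster 7. In thinned cells these were cyp8b1 at 0.113, slc27a2a at 0.668, mical2b at 1.399, insl5a at 0.123, c2cd4a at 0.0435 and uqcrc2a at 0.847 in absorptive cells; zgc:77650 at 5.79 in cluster 17; apoa1b at 0.195 in cluster 4; gip at 0.796 over all cells; prdx1 at 1.62 in cluster 14; tcnba at 1.295 in cluster 6. Without cells over the 98th percentile of UMIs these were penka at 3.65 and c2cd4a at 0.0633 in absorptive cells. In the second clustering these were plac8.2 at 4.87, BX908782.2 at 1.92, penka at 3.88 and pcna at 0.613 in absorptive cells. In clusters made without differing genes these were msmo1 at 0.633 and pcna at 0.624 in absorptive cells. Without the highest doublet scores gip was at 0.0152 over all cells.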

Other observations

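Several genes outside the groups described above also had extreme ratios in these clusters. In best4/otop2-like cluster 0, the dehydrogenase gene dhdhl was at 2.997 [2.097 to 4.37], zanl at 2.28 [1.88 to 2.79] and ssr3, a subunit of the translocon-associated complex of the endoplasmic reticulum, at 2.32 [1.84 to 2.94]. si:dkey-28k24.2 was at 0.105 [0.0581 to 0.177] there, and si:dkey-190j3.2, which leads this cluster, at 0.151 [0.115 to 0.196] in cluster 0 and 0.207 [0.157 to 0.270] in cluster 2. In goblet-like cluster 3, rab11a, which acts in recycling endosomes, was at 0.443 [0.350 to 0.558]. In enteroendocrine-like cluster 12, urahb, a hydrolase of the urate pathway that also leads this cluster, was at 0.450 [0.403 to 0.502]. In unnamed cluster 1, rps27l, a target of p53 in mammals, was at 1.91 [1.75 to 2.09], and lygl1 at 2.06 [1.71 to 2.49]. In unnamed cluster 7, id1 was at 0.318 [0.267 to 0.377].

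The heat shock genes hsp70.1 and hsp70l were lower in best4/otop2-like cluster 2, at 0.286 [0.225 to 0.362] and 0.350 [0.296 to 0.414]. In tuft-like cluster 13 hsp70.3 was at 2.39 [2.04 to 2.82], and at 4.23 without the cells with the highest doublet scores. In unnamed cluster 9 it was at 3.40 [2.72 to 4.27], at 1.99 after thinning and at 1.51 among the stricter cells. Over the clusters measured, hsp70l was lower in 7 and higher in 9 of 22, and CT027638.1 was lower in 5 and higher in 16 of 23. mt-atp6 was higher in 21 and lower in 1 of 23 clusters, and nr0b2a higher in 3 and lower in 1 of 16. Without the 2 highest cells per library, nr0b2a was higher in 2 and lower in 2. tnfb was higher in 4 and lower in 1 of the 7 clusters with enough counts.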
